A study of uncultured bacterium with 48 samples.

How the data were processed

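The series holds 48 samples of genomic DNA from the sludge of full-scale anaerobic digesters at 3 wastewater treatment plants. A digester in Beijing, a digester in Qingdao and both digesters in Ninghai, one run in the mesophilic and one in the thermophilic temperature class per the labels, were each sampled in 12 consecutive months from October 2012 to September 2013. The temperature class of the Beijing and Qingdao digesters is not given in the sources used here. Each group is therefore 1 tank followed over time, and its 12 samples are monthly samplings of that tank rather than separate digesters.

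Per the labels, DNA was extracted with a commercial soil kit, purified with phenol and chloroform, labelled by random priming together with a universal standard DNA and hybridised to GeoChip, an array of oligonucleotide probes for genes of known microbial functions. The labels name Cy5 as the dye of the samples while the labelling protocol names Cy-3, and which dye the deposited values hold is not given in the sources used here. Scanner, background correction, detection rule and normalization are not given in the sources used here.

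The deposited table gives 1 intensity per probe and sample for 94323 probes of 1205 gene families, with the organism from which each probe was designed. The values are linear: they hold decimals, no zeros and no negatives, and a blank stands where a probe has no value, read here as not detected. They share no common total, since the summed intensity of an array ranged from 85772829 to 165776935. The number of arrays limits the precision, and signal over background is not known, because only values above the unknown detection rule are listed. The lowest listed signal differed between arrays.

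For each sample the intensities of a family's probes were summed, with undetected probes as 0, and divided by the array's total. The log2 of this percentage was the family's value. A sum of 0 was replaced by the smallest sum above 0 of that family divided by 2. Families with at least 5 probes and detected in at least 36 of the 48 samples were tested, which left 678 families with 93312 probes. Linear models were fitted with limma 3.58.1 in R 4.3.3 to all 48 samples with 1 mean per tank, and p-values were adjusted with the Benjamini-Hochberg method at a threshold of 0.05. Tanks were compared pairwise and by an F test over the 4 means. Warm months, June to August, were compared with cold months, December to February, over 24 samples with the tank as a covariate, and a season by tank interaction was tested by an F test. Errors of log2 changes are standard errors from limma, and other errors are SD over the 12 samples of a tank.

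Probes of the Ninghai tanks were compared with limma where detected in all 24 samples, and by Fisher's exact test of detection otherwise. Detected probes, the Shannon index and evenness were compared by 2-sided permutation tests with 1e+05 resamples. Bray-Curtis dissimilarities of the array percentages were tested with PERMANOVA, a dispersion test and Mantel tests in vegan 2.7.1 with 9999 permutations. The Mantel tests set dissimilarity against the months between samplings within each tank, and the months were permuted.

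Gene lists for the processes of anaerobic digestion, nutrient cycles, stress and resistance were written, and the comparisons, tests and most alternatives were chosen, before the data were examined. Family names were matched to the lists, and 6 matches were left out because the table files those names under another process. Lists with at least 3 measured families were tested with camera at a preset correlation of 0.01 and at an estimated one, and with fry, over 23 lists and 42 categories of the table per comparison. The lists for methane oxidation, acetogenesis, nitrogen fixation and ammonification were smaller and get values alone, and the sporulation list matched no tested family. Signal on probes of 7 lists of genera was compared by permutation tests. Every genus with at least 20 probes, 656 in all, was also compared with limma on the mean log2 percentage of its probes, each raised to 1 common floor, an addition made after the data were seen. The floor draws log2 changes of a genus toward 0, so percentages of the array signal are printed beside them.

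The pipeline was tested on simulated changes planted into regrouped samples. Tank means were removed and the samples mixed over tanks and months. This left out the likeness of neighbouring months and the unequal spread between tanks that the real data have. The rates below therefore do not cover these features. With 12 samples in each of 2 tanks, 65% of families with a planted log2 change of 0.2 and 94% of those with 0.5 were recovered at 4.43% false calls, and the median number of calls with no change planted was 0. For warm against cold months these were 63.7% and 93.2%, and for single probes 1.4% and 62.4%.

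Alternatives covered no division by the array total, median centring, quantile normalization, the mean log2 over probes detected in all samples, the share of detected probes, other filters, moderation with a trend, a month block, leaving out each month, parts of the year, other dissimilarities and a common floor for all arrays. Figures were drawn with matplotlib 3.10.9.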

Results

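The data cover 48 samples, 12 monthly samplings from each of 4 anaerobic digesters, hybridised to a functional gene array. The series asks how the functional genes of digester communities vary along time and space. An array detected between 46732 and 64926 of its 94323 probes, or 49.5% to 68.8%. The mean number detected was 59854 ± 2122 in Beijing, 53411 ± 3762 in Qingdao, 60286 ± 2882 in the Ninghai mesophilic tank and 61239 ± 1913 in the Ninghai thermophilic tank (SD, n = 12 each). Total signal, in units of 1e+06, averaged 137 ± 10.9, 113 ± 22.9, 127 ± 7.65 and 126 ± 16.0 in the same order. In all, 32568 probes were detected in all 48 samples while 431 were detected in none. Because each group is 1 tank, no p-value below says anything about other digesters of the same kind. Those for differences in signal, diversity or composition set them against the month-to-month spread within these tanks. Camera instead compares a list with the other families, Fisher's test compares detection counts, and the Mantel tests relate dissimilarity to months apart.

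The Ninghai tanks, at one plant and run at different temperature classes, had similar shares of the array signal on most gene families. The family mcra, methyl-coenzyme M reductase of the last step of methane formation, held 0.144% ± 0.00947 of the signal in the mesophilic and 0.151% ± 0.0171 in the thermophilic tank (SD, n = 12 each). The log2 change was 0.07 ± 0.06 (SE), and the thermophilic tank was higher in 7 of 12 months. The nitrogenase family nifh had a log2 change of -0.08 ± 0.04 with an adjusted p of 0.653. For the 22 marker families chosen in advance the changes lay between -0.08 and 0.09, with adjusted p from 0.653 to 0.999. In limma 0 of 678 families passed the threshold, with 48 at an unadjusted p under 0.05, and the median absolute log2 change was 0.04. The 95% interval of the change lay within 1.5-fold for 648 of the 678 families, or 95.6%. These intervals take the monthly samples as independent and use a spread pooled over all tanks. Samples near in time were alike in both Ninghai tanks, so the intervals may be too narrow and do not establish equal content.

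Groups that respond to heat in single organisms did not separate the Ninghai tanks by this test. Of the 8 heat shock families 0 passed over all families or when adjusted over the list alone. The chaperone families dnaK and groEL had log2 changes of 0.06 ± 0.05 and 0.03 ± 0.04, and grpE and the repressor hrcA had changes of -0.05 ± 0.05 and -0.03 ± 0.04. The regulator ctsR had the lowest p of the list, at -0.20 ± 0.08 with an adjusted p of 0.455, and was lower in the thermophilic tank in 11 of 12 months. Of the 4 cold shock families desR, a membrane lipid regulator, passed when adjusted over the list alone, at 0.15 ± 0.05 with an adjusted p over all families of 0.347. One of 12 pectin families, pectate_lyase_Oomycetes at 0.37 ± 0.12, and 1 of 39 metal families, the copper efflux family CusA at -0.22 ± 0.06, passed in that way too. Among the 12 methanogenesis, 5 denitrification, 6 sulfate reduction and 7 starch families 0 passed in either way. The pullulanase family pula came closest of these, at -0.12 ± 0.04 with an adjusted p of 0.347. No list or category passed camera, and pectin degradation was nearest with an adjusted p of 0.147, or 0.154 with an estimated correlation.

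The count of 0 depended on the samplings, the samples fitted, the filter and the summary of a family. In the first 6 samplings alone, October to March, 19 families passed, with 6 after quantile normalization and 0 without division by the array total. All 19 kept their direction in both, with a median of 78.8% and 124% of the log2 change left. In the last 6 samplings, April to September, 1 family passed. With February left out 1 family passed, the 24 Ninghai samples alone gave 6, no filter on families gave 4, and the mean log2 over probes detected in all samples gave 15.

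**Figure D1:**
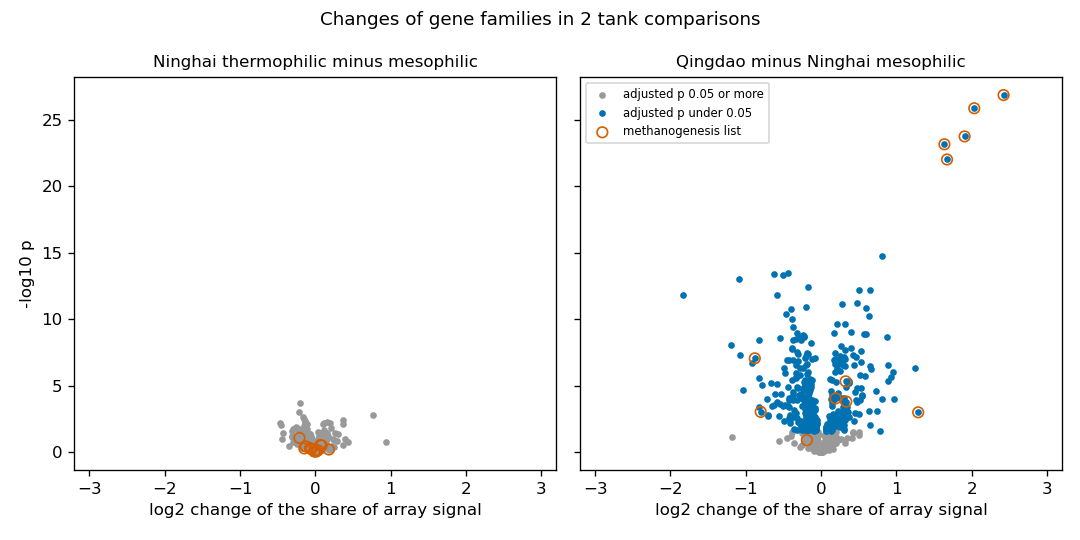
Log2 change of the share of array signal (x axis) against -log10 of the unadjusted p (y axis) for 678 gene families, Ninghai thermophilic minus mesophilic tank on the left and Qingdao minus Ninghai mesophilic tank on the right. Blue points have an adjusted p under 0.05, which are 0 on the left and 347 on the right, and rings mark the 12 methanogenesis families.

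At the level of single probes the Ninghai tanks did differ, by small amounts. Of 41904 probes detected in all 24 samples, 347 were higher and 1493 lower in the thermophilic tank, and only 2 and 11 of these by more than 2-fold. The called probes came from 383 of 912 families, and 146 families held probes of both directions. The multidrug transporter family MFS_antibiotic had 29 higher and 82 lower of 3127 probes, the alpha-amylase family amyA 14 and 53 of 1349, and the nitrite reductase family nirs 5 and 7 of 134. Fisher's exact test of how often a probe was detected gave 0 of 42106 past the threshold and 885 at an unadjusted p under 0.05, with a lowest p of 9.61e-06. Over so many tests a lone probe passes only when detected in 12 of 12 months of one tank and 0 of the other, so this count does not show equal detection. The counts fell to 13 higher and 133 lower without division by the array total, and the excess of lower probes shrank with quantile normalization, which gave 439 and 599. Probes detected in at least 18 of 24 samples gave 389 higher and 2478 lower. For the same 41904 probes the first 6 samplings gave 1115 higher and 5303 lower and the last 6 gave 0 and 1.

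Many more families differed between plants than between the Ninghai tanks, and of the gene lists tested methanogenesis had the largest mean log2 change against the mesophilic tank, 0.83 in Qingdao and 0.46 in Beijing. Mer_methane, the methylene-tetrahydromethanopterin reductase family, held 0.0116% ± 0.00122 of the signal in the Ninghai mesophilic tank, 0.0387% ± 0.00565 in Beijing and 0.0642% ± 0.0186 in Qingdao (SD, n = 12 each). It was 3.32-fold higher in Beijing and 5.37-fold higher in Qingdao, with log2 changes of 1.73 ± 0.10 and 2.42 ± 0.10, while its share of detected probes changed by -0.10 in Beijing. The formylmethanofuran dehydrogenase family fmdB_fwdB was 3.12-fold and 4.10-fold higher, mrtH 2.28-fold and 3.75-fold, the formyltransferase family Ftr 2.21-fold and 3.11-fold and the cyclohydrolase family Mch_methane 1.79-fold and 3.19-fold. Each of these 5 families was higher than in the mesophilic tank in 12 of 12 months at both plants, with adjusted p of 4.34e-10 or lower.

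All 12 methanogenesis families passed the F test over the 4 tanks, and 8 of them were highest in Qingdao. Against the Ninghai mesophilic tank 9 rose and 2 fell in Qingdao, and 7 rose and 3 fell in Beijing, with the same counts adjusted over the list alone. These directions held in each scaling tried. The falls were the methanol methyltransferase family mtaB at both plants, with log2 changes of -0.88 ± 0.14 in Qingdao and -1.10 ± 0.14 in Beijing, mtxX in Qingdao at -0.80 ± 0.23 but 0.04 as the mean log2 over probes detected in all samples, and Hmd and MT2 in Beijing at -0.92 ± 0.37 and -0.39 ± 0.12. Hmd, the hydrogen-forming dehydrogenase family, rose in Qingdao by 1.29 ± 0.37, and mtxX rose in Beijing by 1.13 ± 0.23. The family mcra held 0.182% in both Beijing and Qingdao and rose by 0.33 ± 0.06 at each, but the mean log2 over probes detected in all samples gave -0.0049 and -0.05. The list passed camera with adjusted p of 6.64e-06 in Qingdao and 3.46e-05 in Beijing, lost as adjusted p = 0.191 and 0.273 with an estimated correlation. The fry test, which asks whether the families move one way on balance, gave adjusted p of 1.92e-18 and 1.00e-10. A fit without the probes of the genus Methanosaeta was chosen after the data were seen. It left a mean log2 change of the list of 0.12 in Qingdao and 0.15 in Beijing. In Qingdao Mer_methane was then -0.27, fmdB_fwdB 0.32, mrtH 0.07, Ftr 0.12 and Mch_methane 1.09, with mrtH and Ftr at adjusted p of 0.317 and 0.227. In Beijing the same families were at 0.37, 0.89, 0.34, 0.52 and 0.77. The family mcra stayed at 0.35 at each plant.

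**Figure D2:**
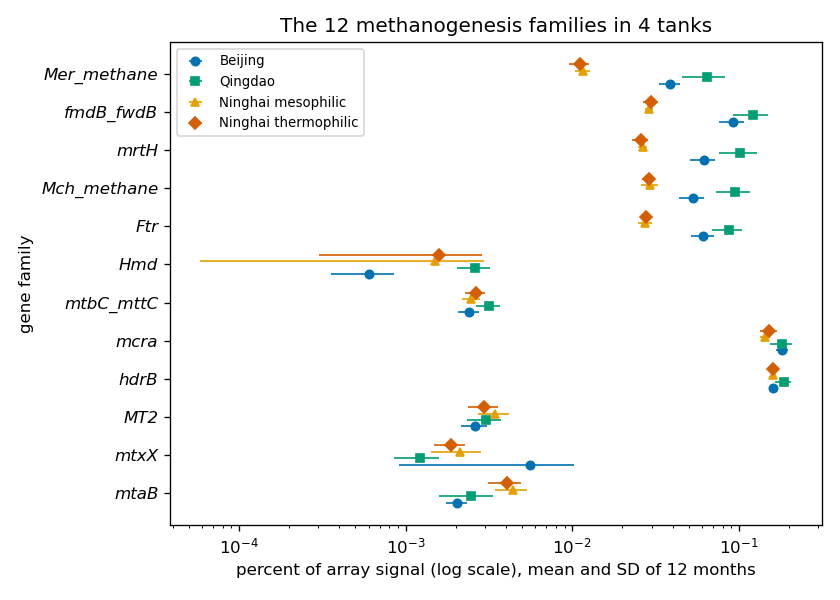
Percent of array signal (x axis, log scale) of the 12 methanogenesis families (y axis) in each tank, as the mean of 12 months with SD bars. Mer_methane reaches 0.0642% in Qingdao and 0.0387% in Beijing against 0.0116% in the Ninghai mesophilic tank.

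Across all functions 500 of 678 families, 73.7%, passed the F test over the 4 tanks. Against the Ninghai mesophilic tank 102 families were higher and 244 lower in Beijing, and 146 were higher and 201 lower in Qingdao. Against the thermophilic tank these counts were 78 and 189 for Beijing and 150 and 190 for Qingdao, and Beijing against Qingdao gave 144 and 237. Most changes were small, since the median absolute log2 change against the mesophilic tank was 0.14 at each plant and 11 and 12 called families changed by more than 2-fold in Beijing and Qingdao. Without division by the array total the median of all families moved from -0.07 to 0.04 for Beijing and from -0.03 to -0.22 for Qingdao. The balance of higher and lower families followed the scaling, since without division 76 were higher and 48 lower in Beijing and 41 and 316 in Qingdao. Of the called families 320 of 346 and 302 of 347 kept their direction in each scaling. Outside methanogenesis the widest ranges belonged to nitrite_reductase_protist, the mercury transport family merE and the aromatic degradation family tdnb. The first had log2 changes of -2.32 ± 0.19 in Beijing and -1.83 ± 0.19 in Qingdao, although the mean log2 over probes gave 0.24 for Qingdao, with an adjusted p of 0.000510. The second rose by 1.36 ± 0.11 in Beijing and fell by 0.43 ± 0.11 in Qingdao, where the share of detected probes gave 0.14. The third passed the F test with no single difference from the mesophilic tank past the threshold.

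In the nitrogen cycle, 5 of 7 families for nitrate assimilation and reduction to ammonium fell in Beijing and 1 rose, and 4 fell in Qingdao with 0 rises, with the same counts adjusted over the list alone. The assimilatory nitrate reductase family nasa held 0.109% ± 0.0139 in the Ninghai mesophilic tank, 0.0760% ± 0.00357 in Beijing and 0.0858% ± 0.00434 in Qingdao, and the periplasmic nitrate reductase family napa fell by 0.29 ± 0.03 and 0.20 ± 0.03. Among 5 denitrification families nirs and norb rose and narg and nirk fell in Beijing, by no more than 0.14 on the log2 scale, and 0 of the 5 passed in Qingdao. The fall of nirk turned to 0.01 without division by the array total and the rise of nirs to -0.04 in the share of detected probes. The nitrogenase family nifh rose by 0.22 ± 0.04 in Qingdao and the ammonia monooxygenase family amoa by 0.27 ± 0.11 in Beijing. Without the Methanosaeta probes nifh was 0.096 in Qingdao, with an adjusted p of 0.0251, and -0.12 in Beijing, with an adjusted p of 0.00518. The glutamate dehydrogenase family gdh rose by 0.41 ± 0.07 in Beijing and 0.59 ± 0.07 in Qingdao, but the share of detected probes gave -0.03 and -0.05, the latter with an adjusted p of 0.0309. The urease family urec fell by 0.07 ± 0.02 and 0.12 ± 0.02, and without division it changed by 0.04 in Beijing. The dissimilatory nitrite reductase family nrfa did not pass the F test, with an adjusted p of 0.464.

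Among carbon degradation families, 3 of 4 for cellulose fell at each plant, with endoglucanase at 0.246% ± 0.0273 in the mesophilic tank against 0.206% ± 0.0106 in Beijing and 0.194% ± 0.00868 in Qingdao. Of 7 starch families 4 fell and 1 rose in Beijing, among them the pullulanase family pula with a fall of 0.32 ± 0.04, while the largest family amyA did not pass the F test with an adjusted p of 0.146. Of 12 pectin families 5 rose and 1 fell in Beijing and 6 rose and 3 fell in Qingdao, of which 5 of 6 and 6 of 9 kept their direction in each scaling, and pel_Cdeg rose by 0.39 ± 0.08 and 0.26 ± 0.08. Of 13 families for lignin and aromatic compounds 1 rose and 3 fell in Beijing, or 0 and 3 adjusted over the list alone, and 5 fell in Qingdao, or 4 over the list alone. The manganese peroxidase family mnp fell by 0.45 ± 0.04 in Qingdao. Of 3 chitin families 2 rose in Qingdao, and of 4 hemicellulose families 1 rose and 1 fell there, with 1 of 2 calls in each list keeping its direction in each scaling. None of these lists passed camera, and cellulose degradation had adjusted p of 0.733 in Beijing and 0.850 in Qingdao. For the acetogenesis enzymes fthfs and codh the changes were -0.16 ± 0.04 and 0.11 ± 0.04 in Beijing and 0.16 ± 0.04 and 0.11 ± 0.04 in Qingdao, where both turned negative without division, to -0.03 and -0.08. Without the Methanosaeta probes codh was -0.16 in Qingdao, with an adjusted p of 0.000802, and -0.0060 in Beijing, where the share of detected probes gave -0.03.

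In the sulfur cycle 1 of 6 sulfate reduction families rose and 1 fell in Beijing and also in Qingdao. The dissimilatory sulfite reductase family dsra rose by 0.08 ± 0.03 and 0.18 ± 0.03, with -0.0068 in Qingdao without division. Without the Methanosaeta probes dsra was 0.03 in Beijing and 0.05 in Qingdao, with adjusted p of 0.523 and 0.220. Its partner dsrB fell by 0.08 ± 0.02 in Beijing, with 0.03 without division. Of 7 sulfur oxidation families 3 rose and 1 fell in Beijing and 2 rose and 3 fell in Qingdao, with sqr, sulfide quinone oxidoreductase, up by 0.23 ± 0.07 and 0.30 ± 0.07 and soxB down at both by -0.44 ± 0.10 and -0.36 ± 0.10. Of 10 carbon fixation families 1 rose and 2 fell in Beijing and 3 rose and 2 fell in Qingdao, among them rubisco with rises of 0.09 ± 0.02 and 0.18 ± 0.02, which was -0.01 in Qingdao without division and -0.03 in Beijing as the mean log2 over probes. In the share of detected probes rubisco changed by -0.04 in Qingdao, with an adjusted p of 0.0328. Without the Methanosaeta probes rubisco was 0.03 in Beijing and 0.0088 in Qingdao, with adjusted p of 0.392 and 0.790. Among 8 heat shock families 4 fell in Beijing, or 5 adjusted over the list alone, and 2 rose and 3 fell in Qingdao. Without division both rises in Qingdao turned to falls, groEL to -0.08 and clpC to -0.06, and 3 of the 4 calls in Beijing kept their direction in each scaling. The family grpE fell by 0.22 ± 0.05 and 0.23 ± 0.05, hrcA fell by 0.23 ± 0.04 in Qingdao, and dnaK did not pass the F test with an adjusted p of 0.620. Of 10 oxygen limitation families 4 rose and 2 fell in Qingdao and 1 rose and 1 fell in Beijing, and of 9 oxygen stress families 2 rose and 3 fell in Qingdao and 1 rose and 3 fell in Beijing. The catalase family katA rose by 0.48 ± 0.05 in Qingdao and 0.16 ± 0.05 in Beijing. Without its 1 Methanosaeta probe katA was -0.02 in Qingdao, with an adjusted p of 0.790, and -0.11 in Beijing, with an adjusted p of 0.0430. The cold shock family cspA fell by 0.25 ± 0.06 in Beijing and rose by 0.17 ± 0.06 in Qingdao, where it was -0.01 without division and -0.18 in the share of detected probes, with an adjusted p of 0.00279. As the mean log2 over probes it was 0.02 in Beijing. Viral families were lower in Beijing for 22 of 49 and higher for 4, and fungal families for 25 and 7 of 67. In Qingdao 12 viral families were higher and 11 lower, and 10 fungal families higher and 15 lower. In Beijing 21 of the 22 lower viral and 25 of the 25 lower fungal families kept their direction in each scaling. Neither list passed camera at either plant, while fry gave adjusted p of 0.000598 and 0.000190 in Beijing. Many of the viral families are of RNA viruses while the samples were genomic DNA, so what bound their probes is not known. Probes for RNA viruses were detected at 45.1% and those for DNA viruses at 45.5%, against 62.2% of all probes. Detection of a probe therefore need not mean that its named gene was present, which also limits the counts of detected probes and the diversity values. How much of the signal on other probes is of this kind is not known. Of 11 antibiotic resistance families 2 rose in Beijing and 2 fell in Qingdao, 1 of the 2 at each keeping its direction in each scaling, and of 39 metal resistance families 8 rose and 10 fell in Beijing and 6 rose and 13 fell in Qingdao. Of 3 phosphorus families phytase rose in Beijing, and ppk did not pass the F test with an adjusted p of 0.826. Of 5 osmotic stress families 1 rose at each plant, and of 5 for nitrification and anammox 1 rose and 2 fell at each.

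Signal by organism followed the plants as well. Probes of acetoclastic methanogens, which make methane from acetate, held 2.04% ± 0.632 of the signal in Qingdao, 0.942% ± 0.213 in Beijing, 0.187% ± 0.0143 in the Ninghai mesophilic and 0.188% ± 0.0455 in the thermophilic tank (SD, n = 12 each). Hydrogenotrophic methanogens were at 0.479% ± 0.107 in Beijing, 0.321% ± 0.0228 in Qingdao, 0.250% ± 0.0208 in the mesophilic and 0.252% ± 0.0213 in the thermophilic tank. Genera known as thermophiles held 2.37% ± 0.270 in the mesophilic and 2.26% ± 0.336 in the thermophilic tank, higher in the thermophilic tank in 4 of 12 months, with p = 0.395 by a permutation test and adjusted p = 0.691 over 7 lists. Aerobic genera of activated sludge were at 5.01% ± 0.0573 and 5.10% ± 0.106, higher in the thermophilic tank in 10 of 12 months, with p = 0.0193 and adjusted p = 0.135. Syntrophic, sulfate-reducing and faecal genera had permutation p of 0.221, 0.364 and 0.556 between the Ninghai tanks. Within a tank the warm and cold months are 3 against 3 samples, for which the smallest exact p is 0.1. Thermophile genera changed by 0.490 percentage points from cold to warm months in the mesophilic tank, with an exact p of 0.1, and by 0.416 in the thermophilic tank, with an exact p of 0.3.

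**Figure D3:**
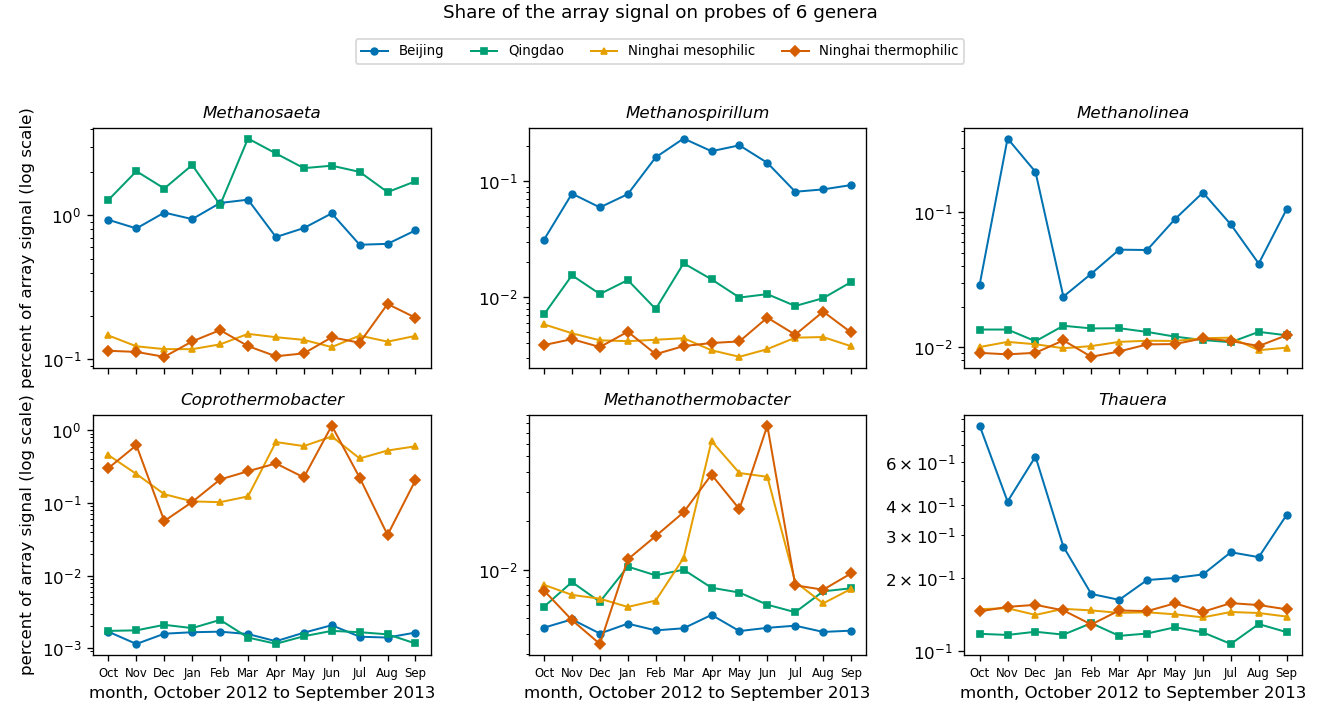
Percent of array signal (y axis, log scale) on probes of 6 genera by month (x axis) in the 4 tanks, with genera chosen after their values were seen. Methanosaeta averages 1.99% in Qingdao and 0.134% in the Ninghai mesophilic tank, and Coprothermobacter 0.403% and 0.315% in the Ninghai tanks against 0.0016% in Beijing.

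Warm and cold months differed in few families in the planned model. The nitric oxide reductase family cnorB rose in the warm months by 0.21 ± 0.04 on the log2 scale, in 4 of 4 tanks, with an adjusted p of 0.0362 (limma, 24 samples). ATP_sulphurylase, which activates sulfate for assimilation, changed by -0.49 ± 0.10, Major_capsid_protein_partitiviridae by -0.29 ± 0.06 and VP4_Pserotype_Rotavirus by -0.33 ± 0.08, each in 4 of 4 tanks, with adjusted p of 0.0362, 0.0376 and 0.0376. Partitiviruses and rotaviruses have RNA genomes while the samples were genomic DNA, so what bound the probes of these viral families is not known. These 4 were the only families past the threshold of 678, with 108 at an unadjusted p under 0.05. Just above it lay nasa at -0.16 ± 0.04 and the cold shock family cspB at 0.14 ± 0.04, both with an adjusted p of 0.0698. The 22 marker families had changes between -0.18 and 0.28 and adjusted p from 0.227 upwards, with mcra at -0.13 ± 0.07. Of the 23 gene lists none passed camera, with the lowest adjusted p of the lists at 0.987. The 4 calls were lost without division by the array total, when January, February, July or August was left out, with no filter on families and in the share of detected probes, while other choices gave more, with 14 after median centring, 16 after quantile normalization, 21 as the mean log2 over probes and 88 with an annual harmonic over 48 samples. The same 3-month blocks moved to other positions on the calendar gave between 2 and 64 families, a test chosen after the data were seen, so the 4 calls are not special to warm and cold months. The share of detected probes turned ATP_sulphurylase to 0.12.

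The change from cold to warm months differed between tanks. The interaction of season and tank passed for 40 of 678 families, with 169 at an unadjusted p under 0.05, and within single tanks limma called 0 families in Beijing, with 80 at an unadjusted p under 0.05, 32 in Qingdao, 11 in the mesophilic and 42 in the thermophilic Ninghai tank. Fitted on its own 6 samples, each tank gave 0, 1, 8 and 20 in the same order. The interaction count was 3 without July and 76 without August, 11 without division by the array total and with quantile normalization, 7 as the mean log2 over probes and 3 in the share of detected probes. The same blocks moved over the calendar gave between 5 and 102 families. The hydroxylamine oxidoreductase family hao, of nitrification, rose by 0.53 and 0.60 in the mesophilic and thermophilic Ninghai tanks and had values of 0.25 in Beijing and -0.18 in Qingdao, with an interaction adjusted p of 0.0264. It was chosen after its values were seen.

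The Shannon index over probes was 9.86 ± 0.0510 in Beijing, 9.88 ± 0.128 in Qingdao, 10.06 ± 0.0781 in the mesophilic and 10.01 ± 0.112 in the thermophilic tank (SD, n = 12 each). The Ninghai tanks differed by -0.0507 in the Shannon index, with a permutation p of 0.213, by 953 detected probes, with p = 0.395, and by -0.00597 in evenness, with p = 0.0425 and an adjusted p of 0.0637 over 6 tank pairs. Qingdao had 6875 fewer detected probes than the mesophilic tank, with an adjusted p of 0.00028, and 6442 fewer than Beijing. Beijing was lower in the Shannon index than the mesophilic tank by 0.202, with an adjusted p of 0.00012. With 1 common detection floor for all arrays the number of detected probes was highest in Qingdao, at 43535, and lowest in Beijing, at 32692, so the order of the tanks depends on the lowest signal listed per array.

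Community composition separated by plant. The 4 tanks accounted for 46.9% of the Bray-Curtis variation (PERMANOVA, p = 1e-04, the smallest that the permutations can give), and pairs of tanks from different plants for 31.1% to 43.2%, each with an adjusted p of 0.00012. The Ninghai tanks differed by 8.20%, with p = 0.0248. The nearest neighbour of a sample belonged to the same tank for 12 of 12 samples in Beijing and in Qingdao, 10 in the mesophilic and 9 in the thermophilic tank. Mean dissimilarity between the Ninghai tanks was 0.129 ± 0.0196, below that within the thermophilic tank, 0.135 ± 0.0234, and above that within the mesophilic tank, 0.111 ± 0.0218, while Beijing and Qingdao differed by 0.235 ± 0.0185. The spread within tanks also differed, with mean distances to the centroid of 0.0915 in Beijing, 0.119 in Qingdao, 0.0750 in the mesophilic and 0.0921 in the thermophilic tank (permutation p = 1e-04), so the tank test includes a difference in spread. The Ninghai difference did not pass on the values as deposited, with an adjusted p of 0.0978, nor with a Euclidean distance, at 0.0843. It did pass on detection alone, with an adjusted p of 0.0082, and on probes detected in all 48 samples, at 0.0363. In the first 6 samplings alone the tanks accounted for 24.9%, with a permutation p of 0.0023, and in the last 6 for 10.8%, with a permutation p of 0.234. These shares come from fewer samples and cannot be set against the 8.20%. Between the Ninghai tanks the mean same-month dissimilarity was 0.123 ± 0.0190 in the first 6 and 0.102 ± 0.0139 in the last 6 samplings (SD over months). That difference had an exact permutation p of 0.0584.

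**Figure D4:**
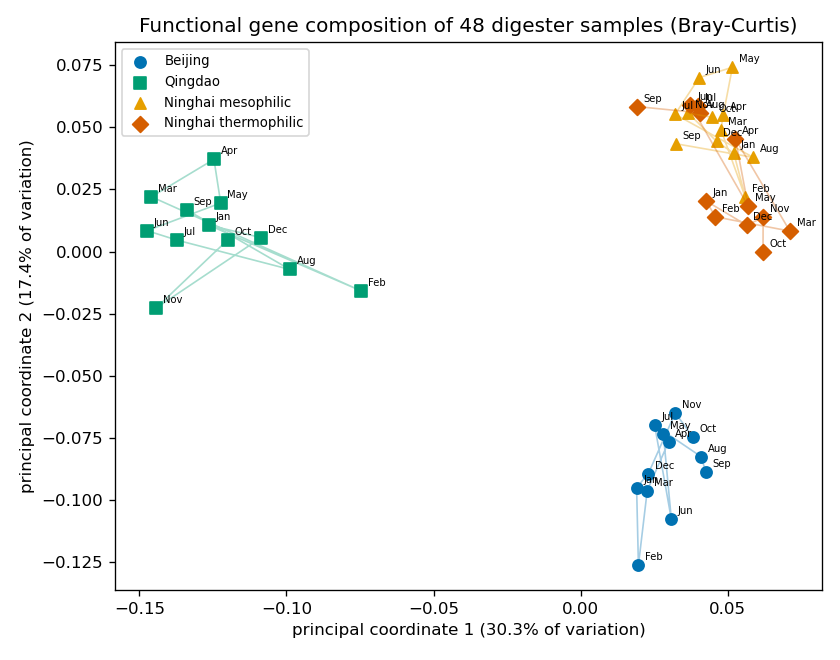
Principal coordinates of Bray-Curtis dissimilarities between the 48 samples, with axes 1 and 2 holding 30.3% and 17.4% of the variation. Each point is a monthly sample, labelled by month and joined in time order within its tank, and the Ninghai tanks overlap while Beijing and Qingdao lie apart.

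Samples further apart in time were less alike in 3 of the 4 tanks. The correlation of dissimilarity with the months between samplings was 0.648 in the thermophilic and 0.549 in the mesophilic Ninghai tank, both with an adjusted p of 2e-04, 0.252 in Beijing with an adjusted p of 0.0476, and 0.128 in Qingdao with 0.195 (Mantel tests, Pearson, 12 samples each). Spearman correlations were 0.689, 0.552, 0.363 and 0.130 in the same order, with adjusted p of 2e-04, 2e-04, 0.0132 and 0.170. Without the first and the last month the Pearson values were 0.647, 0.603, 0.319 and 0.265, with adjusted p of 6e-04, 6e-04, 0.0423 and 0.0614. In the thermophilic tank mean dissimilarity went from 0.106 ± 0.0185 at 1 month apart to 0.156 ± 0.0107 at 6 months. On a circular calendar, where October and September are neighbours, Beijing had a correlation of 0.631 and Qingdao one of 0.270, with adjusted p of 0.000133 and 0.0016. The Pearson relation fell short of the threshold on the values as deposited in the thermophilic tank, with 0.194 and an adjusted p of 0.174, and in Beijing, with 0.263 and an adjusted p of 0.0650. Beijing also fell short on detection alone, with 0.129 and an adjusted p of 0.144, and on probes found in all 48 samples, with 0.243 and 0.0505. In Qingdao detection alone gave 0.356 with an adjusted p of 0.0143.

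**Figure D5:**
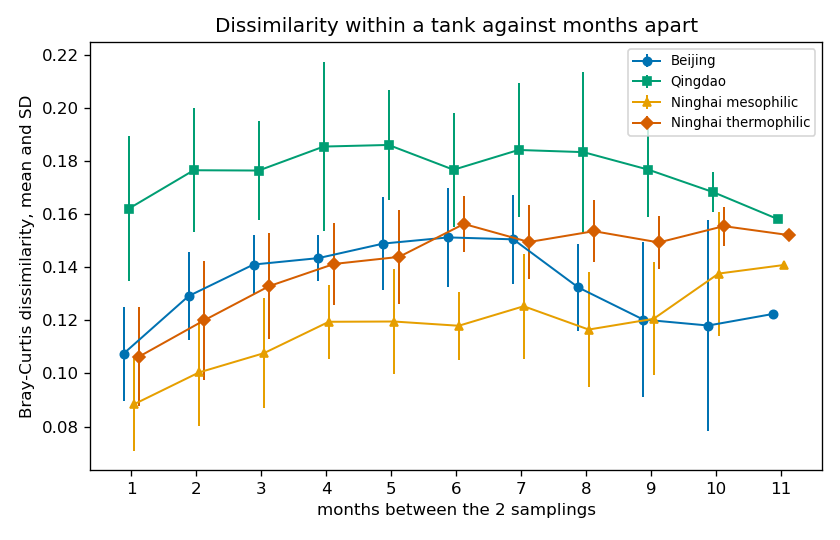
Mean Bray-Curtis dissimilarity (y axis) of samples of the same tank against the months between them (x axis), with SD bars over the pairs. Values in the Ninghai tanks go from 0.0884 and 0.106 at 1 month apart to 0.118 and 0.156 at 6 months, and Beijing returns to 0.118 at 10 months.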

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

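The tests of single explanations below were chosen only after the results were seen, and the season by tank interaction was planned.

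The change from cold to warm months differed between tanks in 40 of 678 families by the interaction test. The families bacA, superoxide_dismutase_fungi, cdtB, sulfate_transporter_protist and Van, chosen after their values were seen, fell in the warm months in both Ninghai tanks, with log2 changes of -1.60, -0.98, -0.83, -1.11 and -0.74 in the mesophilic and -0.76, -0.92, -0.97, -0.93 and -0.67 in the thermophilic tank. In Qingdao papB and VP7_Gserotype_Rotavirus, the latter a family of an RNA virus measured in genomic DNA, fell by 1.46 and 1.44. The count depended on single months and on the measure, with 3 families without July, 76 without August, 11 without division by the array total and with quantile normalization, 7 as the mean log2 over probes and 3 in the share of detected probes. Among other assignments of warm and cold to the samples the highest count was 21 against the real 40, with 1 of 100 as large. Those assignments mix months, so slow drift over the year was tested by moving the 3-month blocks over the calendar. Of 6 positions 4, the real one included, gave at least 40 families, with 102 as the highest, so slow drift within tanks may explain the count and it is not shown to belong to warm and cold months. Within a single tank the 10 splits are too few for a share under 0.05. The real counts and the highest others were 0 and 7 in Beijing, 32 and 59 in Qingdao, 11 and 1 in the mesophilic and 42 and 0 in the thermophilic tank.

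The difference between the Ninghai tanks itself differed between the first and last 6 samplings, with 26 families past the interaction of tank and time of year against 2 in the highest other split (1 of 100 as large), but these splits mix months. Slow drift over the year cannot be told apart: of 6 positions of the 6-month blocks on the calendar only 1, the real one, gave as many, with 0 as the highest other, but 6 positions are too few to decide. The split was also chosen after the data were seen. In the first 6 samplings 19 families passed, 5 higher and 14 lower in the thermophilic tank, among them pel_Cdeg at 0.48 ± 0.10, sqr at 0.38 ± 0.08 and vip at -0.27 ± 0.06. Of these 19 families 13 had under 33% of that size in the last 6 samplings, and 9 had the same sign there. The families were picked for passing in the first 6, so smaller values in the last 6 can follow from this choice alone.

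Several technical explanations of this pattern were tested. Other splits of the 12 samples of the first 6 samplings gave at most 5 families. Of 100 sets of 6 months only the real set, 1 of 100, reached 19, with 5 as the highest other. The real set is 6 months in a row picked after its result was seen, while the other sets were drawn at random. Samples near in time were alike in both Ninghai tanks, so its rank among these sets decides little. Of the 12 runs of 6 months, wrapping from September to October, 1 reached 19, with 2 as the highest other, which are too few runs to exclude slow drift. Dim probes near the detection floor are not the whole cause of the family differences, because 14 of 402 families passed when summed over the 20952 brighter probes of those detected in all 24 samples, against 1 of 425 over as many dimmer ones. As many probes drawn at random, 20 times, gave 3 to 30 with a median of 15.5. The dimmer probes, at a median of 2.42 times the lowest listed signal against 7.46 times for the brighter, did carry most of the single probes called in these months. Overall brightness or scaling of the arrays cannot be told apart, since 6 families passed after quantile normalization, 10 after median centring and 0 without division by the array total. All 19 families kept their direction in each of these. The median share of the log2 change left was 78.8% after quantile normalization, 83.1% after median centring and 124% without division. Without division the calls were thus lost although the median change did not shrink. A batch of thermophilic arrays cannot be told apart from a change in the tank: all 7 thermophilic arrays of October to April had a lowest listed signal, 188 to 270, under that of every mesophilic array, 287 to 427, and no label gives the hybridisation batch. The temperature class, which the design names, stays open and untested within these months.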

How the results depend on the processing

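The split of the year into the first and last 6 samplings, the removal of 3 arrays, the common floor, the probes detected in all 48 samples, the removal of Methanosaeta probes, the Ninghai samples alone with a month block and, for probes, quantile normalization were tests chosen after the data were seen. The sum of values as deposited equals the main measure, because the values are linear, and adds no separate value.

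Most counts moved by less than 1.5 times. Of 55 values of the Ninghai family comparison 39 did so and 16 did not, of 275 for the plants 249 and 26, of 39 for season 7 and 32, and of 16 for probes 6 and 10. For a set of the families named in the report, values counted as unchanged when they stayed on their side of the threshold without a reversal. A change of sign counted as a reversal only where the report's or the alternative value passed the threshold. Unchanged were 777 of 783 values of the Ninghai comparison, 741 of 821 for Beijing, 747 of 821 for Qingdao and 350 of 390 for season. No Ninghai family passed in the report, so the Ninghai count shows little about direction. Against the Ninghai mesophilic tank 16 reversed in Beijing and 23 in Qingdao, and 1 reversed in season. For the changes below the cause was not tested, except where fewer samples or families were used.

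For the Ninghai families, 0 in the report, the count was 15 with the mean log2 over probes detected in all samples, 4 with no filter on families, 1 without probes detected in under 12 samples, 1 with a common floor, 1 without the 3 arrays, 6 with the 24 Ninghai samples alone and 9 with a month block as well. It was 19 in the first 6 and 1 in the last 6 samplings, and 0 to 1 when each month was left out in turn, with 1 without February.

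In the report Beijing had 102 families higher and 244 lower than the mesophilic and 78 and 189 than the thermophilic tank, Qingdao 146 and 201 and 150 and 190, and Beijing against Qingdao gave 144 and 237. Without division by the array total these were 76 and 48, 76 and 30, 41 and 316, 41 and 243, and 356 and 38. Quantile normalization gave 130 and 157 and 101 and 129 for Beijing and 192 and 173 for Beijing against Qingdao. With the mean log2 over probes, Qingdao had 256 higher and 131 lower against the mesophilic and 304 and 117 against the thermophilic tank, and Beijing had 156 higher against the thermophilic tank. In the share of detected probes the F test gave 322, Beijing had 36 higher and 30 lower against the mesophilic and 20 and 16 against the thermophilic tank, Qingdao had 128 lower against the mesophilic tank, and Beijing against Qingdao gave 111 lower. With no filter, which tests more families, the F test gave 845, Beijing had 371 and 287 lower against the mesophilic and thermophilic tank, Qingdao had 263 and 271 higher, and Beijing against Qingdao gave 464 lower.

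The 4 season families became 0 without division, 14 with median centring, 16 with quantile normalization, 21 with the mean log2 over probes, 0 in the share of detected probes, 0 with no filter, 10 without probes detected in under 12 samples, 1 with a trend and robust moderation, 88 with an annual harmonic and 1 with May to October against November to April. Single tanks, with fewer samples, gave 0 in Beijing, 1 in Qingdao, 8 in the mesophilic and 20 in the thermophilic tank. When each month was left out the count was 0 to 1, with 0 without January, February, July or August and 1 without June or December. The interaction, 40 in the report, gave 11 without division, 11 with quantile normalization, 7 with the mean log2, 3 in the share of detected probes, 17 without the 10% lowest values of each array and 13 with May to October against November to April. It ranged from 3 without July to 76 without August.

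Named families reversed as follows, as log2 changes against the mesophilic tank. Without division, Beijing gave dsrB 0.029, nirk 0.012 and urec 0.035, and Qingdao gave codh -0.080, groEL -0.084, fthfs -0.030, cspA -0.015, rubisco -0.0081 and dsra -0.0068. With the mean log2 over probes, Beijing gave mcra -0.0049, rubisco -0.034, dnaK -0.12, cspA 0.016 and pmoa 0.16, and Qingdao gave mcra -0.050, dsrB 0.055, amoa 0.34, ppk 0.076, pmoa 0.18, nitrite_reductase_protist 0.24 and mtxX 0.039. In the share of detected probes, Beijing gave nirs -0.040, rubisco -0.0013, codh -0.032, dnaK -0.11, groEL 0.078, Mer_methane -0.10 and gdh -0.031. There Qingdao gave nosz -0.037, rubisco -0.038, fthfs -0.022, codh -0.0061, groEL -0.016, cspA -0.18, merE 0.14 and gdh -0.053, and season gave ATP_sulphurylase 0.12. Without Methanosaeta probes codh was -0.0060 in Beijing and -0.16 in Qingdao, and Mer_methane was -0.27 in Qingdao. The family katA, outside the counts above, was then -0.11 in Beijing and -0.017 in Qingdao.

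For probes of the Ninghai tanks, 2478 were lower when detection in at least 18 of 24 samples sufficed, 784 higher and 2578 lower with a month block, 13 and 133 without division, 599 lower with quantile normalization, 1183 and 6212 in the first 6 and 0 and 1 in the last 6 samplings, each over the probes detected in all 12 samples of those months.

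With a common floor the detected probes differed by -2697 between the Ninghai tanks, -7203 and -4506 between Beijing and the mesophilic and thermophilic tank, 3639 and 6336 for Qingdao, and -10843 between Beijing and Qingdao. The Shannon index then differed by -0.0403 and 0.0495 for Qingdao against the mesophilic and thermophilic tank and by -0.231 between Beijing and Qingdao, and evenness by -0.0109, -0.00867 and 0.00238. Evenness between the Ninghai tanks passed, at -0.00617, without probes detected in under 12 samples. With sign flips of month differences the Shannon difference of -0.131 between Qingdao and the thermophilic tank had an adjusted p of 0.0564. The Ninghai R2 of 0.0820 was 0.0665 on values as deposited, 0.0640 with a Euclidean distance and 0.108 in the last 6 samplings, none past the threshold, while it passed at 0.249 in the first 6 samplings. It also passed with Jaccard distances and on probes in all 48 samples. With permutations within the calendar month its adjusted p was 0.00244.

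The correlation with months apart lost its call in Beijing with Jaccard distances, 0.129, on values as deposited, 0.263, and on probes in all 48 samples, 0.243, and in the thermophilic tank on values as deposited, 0.194. Qingdao passed with Jaccard distances, 0.356, and on a circular calendar, 0.270. With an estimated correlation camera called 0 lists in each of the 4 comparisons of Beijing or Qingdao with a Ninghai tank.

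The tanks share calendar months. Same-month correlations of the Ninghai tanks ran from 0.00527 to 0.608, were above the median of other months in 12 of 12 months, and were over 0.1 in 9 and not in 3. The same month was the best partner in 5. Because a correlation over 0.1 in every month was required, the month block stayed an alternative. The main Ninghai tests therefore leave out the likeness of same-month samples seen here, and its source was not tested. Apart from the values with a month block or sign flips given above, the block changed no call.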

Other observations

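Methanosaeta, a methanogen that uses acetate, held 1.99% ± 0.632 of the array signal in Qingdao and 0.903% ± 0.214 in Beijing against 0.134% ± 0.0122 and 0.139% ± 0.0416 in the mesophilic and thermophilic Ninghai tanks (SD, n = 12 each). Coprothermobacter, known as a heat-loving degrader of proteins, showed the opposite, with 0.403% ± 0.255 and 0.315% ± 0.308 in the mesophilic and thermophilic Ninghai tanks and 0.00156% ± 0.000239 and 0.00167% ± 0.000372 in Beijing and Qingdao. Both genera, and the others named here, were chosen after their values were seen. The tests of single explanations here were chosen only after the results were seen, as was the comparison of genera, while the comparisons of tanks were planned.

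The mean rise of the methanogenesis list in Qingdao and Beijing may rest mostly on Methanosaeta, but not the rise of each family. The family mcra was 0.35 at each plant without these probes, with adjusted p of 1.76e-05 in Qingdao and 2.17e-05 in Beijing, against 0.33 with them. Without its probes 14.3% of the mean log2 change of the list was left in Qingdao, with 5 families rising and 4 falling, and 32.7% in Beijing, with 7 rising and 4 falling. The mean left was 0.12 ± 0.65 in Qingdao and 0.15 ± 0.69 in Beijing (SD over 12 families). Its unadjusted camera p was 0.236 and 0.000898 at the preset correlation and 0.429 and 0.0298 at an estimated one, in the same order. The unadjusted fry p was 0.00573 in Qingdao and 4.00e-06 in Beijing, so the list still moved on balance without these probes. Sequences of other organisms on conserved methanogenesis probes are argued against, because 100% and 97.7% of the Methanosaeta concilii probes outside the list were more than 4-fold higher in Qingdao and Beijing. The other species did not rise in this way, with 0 of 26 probes of Methanosaeta harundinacea outside the list at either plant and 0 of 33 of Methanosaeta thermophila in Beijing and 1 of 33 in Qingdao. Division by the array total is argued against as well, because 6 and 7 families of the list still rose without it. Which trait of the plants goes with Methanosaeta was not tested, since each plant is 1 tank.

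The Coprothermobacter signal may come from cells present in both Ninghai tanks. A few probes binding other sequences is argued against by 24 of 27 probes more than 4-fold higher, and swapped samples between the Ninghai tanks by 0 Ninghai samples at or under the highest sample of the other plants. The higher operating temperature class alone is argued against, because the thermophilic tank was higher in only 4 of 12 months. A source shared by the Ninghai tanks cannot be told apart from separate growth, since the monthly levels of these tanks had a Spearman correlation of 0.406 over 12 months with a one-sided permutation p of 0.0989.

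For the differences between tanks other than the Ninghai families, other groupings of the same samples gave fewer calls. In each case 1 of 100 splits, the real one included, was as large. These splits mix months and leave out the likeness of samples near in time, so they do not exclude slow drift within tanks. A batch of arrays is not excluded by them either. The real counts and the highest others were 500 and 38 for the F test, 346 and 142 for Beijing and 347 and 47 for Qingdao against the mesophilic tank, and 267 and 137 for Beijing and 340 and 95 for Qingdao against the thermophilic tank. They were 381 and 204 for Beijing against Qingdao, 576 and 2 for genera over the 4 tanks, and 1840 and 10 for probes of the Ninghai tanks. For the 4 season families 2 of 100 splits were as large, with 4 as the highest other. Slow drift over the year may explain them, because 5 of 6 positions of the 3-month blocks on the calendar gave at least as many, with 64 as the highest. For Ninghai families this comparison decides nothing, since the real count was 0 and so 100 of 100 splits gave as many, with 21 as the highest.

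In Beijing Methanospirillum held 0.119% ± 0.0635, with a peak of 0.233% in March, against 0.0118% in Qingdao, and Methanolinea held 0.0999% ± 0.0942, with a peak of 0.351% in November. Methanothermobacter reached 0.0621% in April in the mesophilic and 0.0773% in June in the thermophilic Ninghai tank. Nitrospira reached 0.321% in July in the thermophilic tank. Probes for RNA viruses were detected at 45.1%, near the 45.5% of those for DNA viruses, although the labels name DNA as the material. Over all probes 62.2% were detected, so detection alone does not show that the named gene was present.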
